A study of Homo sapiens with 6 samples.

How the data were processed

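Total RNA of SY5YtetCASZ1b cells was measured on 1-colour Agilent expression arrays. These are cells of the human neuroblastoma line SH-SY5Y in which tetracycline switches on CASZ1b, a form of the zinc finger transcription factor CASZ1. The series holds 6 arrays: 3 of cells given tetracycline at 1 µg/ml for 24 h and 3 of control cells without it. Per the labels, the arrays come from 3 independent experiments, and titles number the replicates 1 to 3 in each group. Every array carried RNA of cells that hold the CASZ1b construct, so an effect of tetracycline itself cannot be separated from that of the induced protein.

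Per the file headers, the authors scanned arrays of design 014850 and extracted them with Agilent Feature Extraction 9.5.3.1. The submitters' processing notes also name Partek 6.6. The deposited scanner files give, per spot, the raw mean and local background intensity, flags, and a processed signal from which Feature Extraction had already removed background and spatial trends, with low values replaced by a surrogate. That processed intensity was not scaled between arrays, per the file headers. The deposited value table holds a ratio: on all 6 arrays, 100% of its 41000 values lay within 0.1% of the mean processed signal of a probe divided by that array's 75th percentile, so its scale is linear, it is not centred on genes, and its direction is that of signal. Its medians were 0.136, 0.141 and 0.0941 for tetracycline replicates 1 to 3 and 0.131, 0.142 and 0.125 for control replicates 1 to 3. Any step made in Partek after this table is not given in the sources used here.

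Each array had 43376 spots that were not controls, for 41000 probes. Spots with a non-uniformity or population outlier flag were left out and the spots of a probe were averaged. Values were log2 of the processed signal minus the array's 75th percentile. A probe entered if it was well above background on all 3 arrays of at least 1 group, which 24510 probes met. Where a gene had several probes, the one with the highest mean over all arrays was kept, leaving 18330 genes (features without a gene name counted as genes of their own). Probes were named through a RefSeq gene table: 23865 by accession, 2004 by symbol and 965 by an older symbol, while 14166 kept the name in the file. Probe coordinates are those of the files, in hg18, a build that only the headers of the replicate 3 files name.

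The 75th percentile of the processed signal was 1619, 1486 and 1438 on tetracycline arrays 1 to 3 and 1466, 1515 and 894 on control arrays 1 to 3. Probes well above background made up 66.6%, 66.3%, 63.9%, 70.1%, 65.9% and 55.8% of the total in the same order. The slope of the spike-in RNAs was 0.724 on control array 3 and between 0.927 and 0.982 on the others. The spike-in coefficient of variation was 13.4% and 10.4% on tetracycline and control array 3 and at most 3.11% on the other arrays. No pair of arrays held identical values. The number of arrays limits the precision.

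The arrays were scanned in 2 periods: replicates 1 and 2 of both groups in period 1 and replicate 3 of both groups in period 2. Slide 1 held tetracycline arrays 1 and 2 with control array 2, and the other arrays came from a slide each. The first principal component, with 78.1% of the variance, separated replicate 3 from the others. Deviations from the group means correlated across 18313 genes between same-numbered arrays, with r of 0.785, 0.815 and 0.838 for replicates 1, 2 and 3, and every array correlated best with its own number. Within period 1, arrays of unlike number correlated at 0.551 and 0.599. The difference between tetracycline arrays 1 and 2 correlated at 0.63 with that between control arrays 1 and 2. For replicate 3 the number and the scan period cannot be told apart. The numbers were therefore taken to pair the arrays. The pairing rests on this check and on the 3 independent experiments of the design text. Blocked values stand beside results where they change the call.

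Genes were tested with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined had no block. A fit with the replicate number as a random block (duplicateCorrelation, consensus correlation 0.887), also chosen before the data were examined, is called the paired test, and a fit with a fixed block was chosen with it. Reporting the paired test as a result of its own was decided after the data were seen. Gene lists were 43 sets fixed before the data were examined. For 42 of them at least 5 members were tested, with camera (preset correlation 0.01), camera with an estimated correlation, and directional fry, to which fry for changes in either direction was added after the data were seen. The list of mitochondrial DNA-encoded genes had 0 members tested. Counts adjusted over the list alone use the paired p-values.

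Named genes followed a rule written before the data were examined: CASZ1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and members of 9 lists (neurotrophin and GDNF receptors and ligands, catecholamine handling, adrenergic transcription factors, neuronal cytoskeleton, striated muscle, endothelial genes, G1/S, G2/M and the integrated stress response) and of the 6 other lists with the smallest camera p. Without pairing no gene passed, for which the rule names the 5 genes with the smallest p in each direction. The other parts of the rule were then applied to the paired test, which was decided after the test without pairing had called none. Where a probe was not well above background on any array of a group, the fold is a bound ("at least"): the mean log2 value of the bright group against the mean, over the arrays of the dim group, of the higher of the probe's own value and the lowest value of any probe well above background on that array.

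The tests were checked on simulated arrays with the real gene means and replicate effects, in which 200 of 18313 genes were changed. Noise was drawn independently for each gene and array, with a gene's spread the same on every array. For the tetracycline comparison, over 4 simulations, the paired test recovered 57.5%, 94.5%, 98.5% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale, and 13.2% of its calls were false, above the 5% aimed at. Without pairing, 0%, 1%, 30% and 53% were recovered, with 0 false calls. The fixed block recovered 27%, 91%, 97% and 97%, with 6.43% of its calls false.

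Alternatives were normexp background correction (offset 50), quantile and median scaling, no filter, a filter on all 6 arrays, the mean of a gene's probes, every probe on its own, an intensity trend with a robust prior, array weights, replicate and slide blocks, the deposited value table, a floor of 16, and leaving out each array. Scan period as a block, period 1 alone, slide 1 alone, slide as a random block, and the alternatives combined with the random replicate block were added after the data were seen. Array weights were estimated by REML on genes with no missing value, in place of a gene-by-gene estimate that depended on the order of the genes; this was changed after its counts were seen.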

Results

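Gene expression was compared between SY5YtetCASZ1b neuroblastoma cells given tetracycline for 24 h, which switches on the zinc finger transcription factor CASZ1b, and the same cells without tetracycline. There were 3 arrays per group from 3 experiments, each array measuring 41000 probes, of which 55.8% to 70.1% were well above background. The series title puts the question as the transcriptome of CASZ1b in neuroblastoma cells.

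The induced gene, CASZ1, was higher with tetracycline in every experiment, by 6.11-fold, 7.67-fold and 18.0-fold. Its only probe (Entrez gene 54897, chromosome 1, 10641527 to 10641579, hg18) gave processed signals of 669, 1371 and 11200 in tetracycline replicates 1, 2 and 3 and of 99.2, 182 and 387 in control replicates 1, 2 and 3. On the log2 scale relative to the 75th percentile of the array, the level was -2.72 ± 1.37 (SD, n = 3) in control cells and 0.52 ± 2.19 (SD, n = 3) with tetracycline, a difference of 3.24 (SE 0.40 in the paired test, limma with the replicate number as a random block). CASZ1 rose in the paired test (adjusted p = 0.0264). It did not pass without pairing (adjusted p = 1.00, exact two-sided permutation p = 0.2, smallest possible 0.1), where tetracycline replicate 1 lay just below control replicate 3. With the replicate as a fixed block its adjusted p was 0.155, with scan period as a block 0.164, and within scan period 1 and within slide 1, which held a single control array, the log2 fold changes were 2.77 and 2.36. Without tetracycline replicate 2 or 3, or control replicate 1, 2 or 3, the paired adjusted p was 0.0913, 0.328, 0.0625, 0.0910 or 0.440, and without the filter on dim probes 0.285. Whether the probe lies in the part of CASZ1 that the construct carries is not known.

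Beyond CASZ1, HTR3A, a serotonin-gated ion channel subunit, rose 91.7-fold and NGFR, the low-affinity neurotrophin receptor, 12.4-fold in the paired test. The monoamine transporters SLC18A1 and SLC6A2 and the oncogene MYCN rose 5.47-fold, 4.88-fold and 5.32-fold, although another MYCN probe had a log2 fold change of only 0.88 and did not pass. The Wnt antagonist DKK2 fell at least 16.7-fold, and the R-spondin receptor LGR5 and IGFBP3, a carrier of insulin-like growth factors, were 11.9-fold and 10.9-fold lower. The paired test called 333 of 18330 genes, 205 higher and 128 lower with tetracycline, and 267 of them changed at least 2-fold. The balance between higher and lower calls varied, with 47.4% to 81.8% of the calls higher when single arrays were left out. All 333 genes went the same way in all 3 experiments, which a small p in pairs favours, as did 41.5% of all genes tested. The groups did not overlap for 248 of the 333, and for 6.47% of all genes tested. By chance 10% of all genes would be expected if the arrays were interchangeable.

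Without pairing limma called 0 genes, with 432 at an unadjusted p under 0.05, and the smallest adjusted p was 0.219. The fixed replicate block called 0 genes, with 2606 at an unadjusted p under 0.05. It pairs the arrays as well, but leaves 2 residual degrees of freedom, against 4 in the paired test. Pairing by itself therefore did not give the 333 calls. With scan period as a block 14 genes were called, and within period 1 none (1332 at an unadjusted p under 0.05), while period 2 held 1 array per group. The paired count of 333 was 181, 33 and 0 without tetracycline replicate 1, 2 and 3, 152, 51 and 0 without control replicate 1, 2 and 3, and 1 without the filter on dim probes. It was 202 after quantile normalization, 184 after median scaling and 3559 with array weights. Of the 52 genes that the naming rule takes and that passed, 33, 14 and 0 were still called without tetracycline replicate 1, 2 and 3, and 31, 15 and 0 without control replicate 1, 2 and 3. In simulations 13.2% of the paired calls were false. Noise there was independent between genes and equal in spread across arrays, and the fixed block called 166.8 genes on average, against 0 in the data. The false share of the real calls can therefore differ. Each "rose", "fell", "higher" or "lower" of a single gene below refers to the paired test, and none of these calls was made without pairing or with the fixed block.

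**Figure D1:**
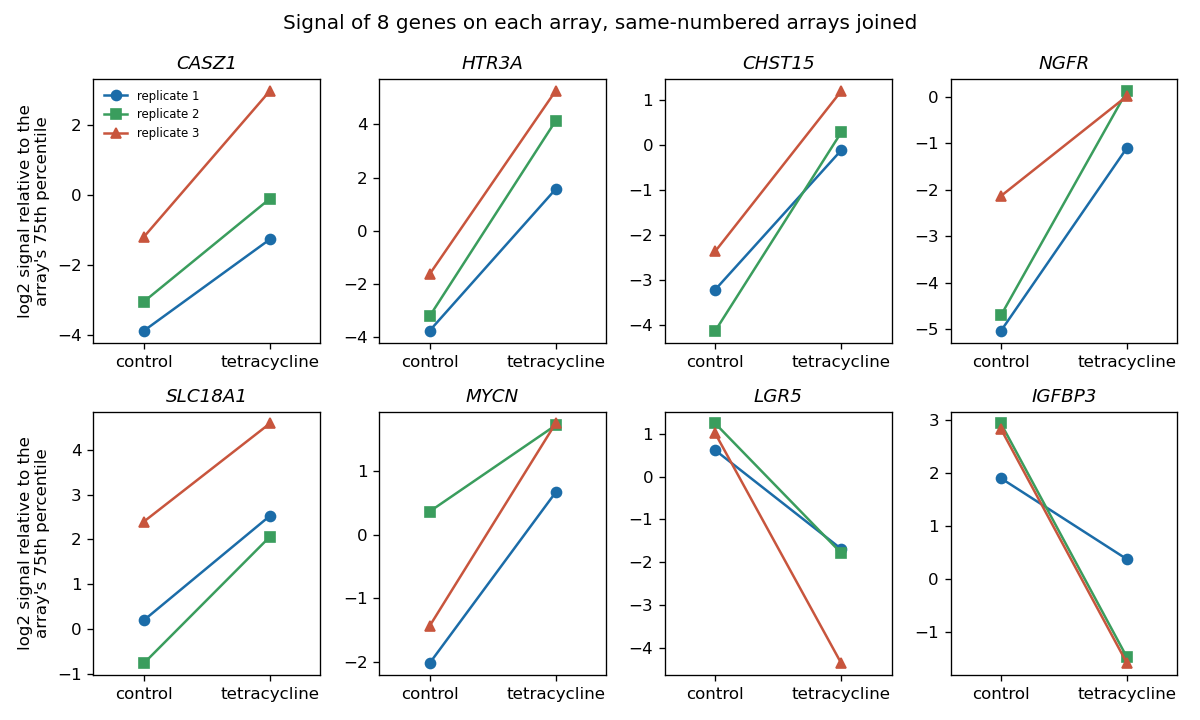
Log2 signal of 8 genes relative to the 75th percentile of each array (y axis, log2 units) in control and tetracycline arrays (x axis); each point is 1 array and lines join arrays of the same replicate number. CASZ1 was higher with tetracycline in each pair, by log2 differences of 2.61, 2.94 and 4.17, and LGR5 lower, by -2.31, -3.03 and -5.37.

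Among the largest rises, HTR3A had a log2 level of -2.87 ± 1.10 (SD, n = 3) in control cells and 3.65 ± 1.89 (SD, n = 3) with tetracycline. The log2 fold change was 6.52 (SE 0.43, adjusted p = 0.0060), with pair values of 5.32, 7.34 and 6.89, and another probe gave 5.77. APOA1, the main protein of high-density lipoprotein, rose 32.2-fold, and HS3ST2, a heparan sulfate sulfotransferase, rose 17.5-fold. COLQ, the collagen tail of acetylcholinesterase, rose 15.7-fold. Each of these last 3 was well above background on 1 of 3 control arrays. KLHDC8A rose 13.8-fold and was well above background on 2 of 3 control arrays. CHST15, a chondroitin sulfate sulfotransferase, rose 12.9-fold (adjusted p = 0.0073). NGFR went from -3.96 ± 1.59 to -0.32 ± 0.68 (SD, n = 3). The control level of 5 others was not well above background, so their rises are bounds. AGT, which encodes angiotensinogen, rose at least 11.1-fold, LOC400573 at least 6.91-fold and SH3TC2 at least 6.23-fold. FGF1, a fibroblast growth factor, rose at least 6.05-fold and CD79B, a B cell receptor component, at least 5.46-fold.

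Among the largest falls, DKK2 fell at least 16.7-fold (adjusted p = 0.0176), a bound, as it was not well above background on any tetracycline array. Another DKK2 probe had about the same difference but did not pass (adjusted p = 0.0621). The transmembrane protein SLITRK6 was 12.7-fold lower and LGR5 went from 0.95 ± 0.32 to -2.61 ± 1.51 (SD, n = 3; log2 fold change -3.57, SE 0.55, adjusted p = 0.0404). The tetraspanin TSPAN8 had a log2 fold change of -3.46 (SE 0.44) and IGFBP3 one of -3.45 (SE 0.55). The gap junction protein GJA1 was 9.74-fold lower, CPED1 9.52-fold, the phosphatase PTPRE 8.54-fold and ARHGDIB 7.43-fold. SLITRK6 and TSPAN8 were well above background on 2 of 3 tetracycline arrays, and GJA1, CPED1 and PTPRE on 1. The other 3, with no tetracycline array well above background, were at least 3.98-fold (TGFB3), 3.54-fold (FAM124B) and 3.02-fold (DSCAML1) lower, although another TGFB3 probe was well above background with tetracycline. Without pairing, the genes with the smallest p among those higher with tetracycline were SH3TC2, SOAT2, AGT, DOK7 and CHST15, and among those lower MAPK10, FAM124B, KIAA1345, PTGER2 and LINGO2. None of these 10 passed without pairing, where adjusted p was 0.219 for SH3TC2 and 0.909 for the other 9.

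Genes of the neuronal and neuroblastoma lists moved in both directions. Of 17 neurotrophin and GDNF receptors and ligands tested, 2 rose and none fell, with NGFR at a log2 fold change of 3.64 (SE 0.48). The counts adjusted over the list alone were 3 and 0, and the list had a median of 0.15 (camera adjusted p = 0.0930). It was called higher without the filter on dim probes (adjusted p = 0.0219), with array weights (0.0175), and without tetracycline replicate 1 (0.0196) or control replicate 3 (0.0115). Its median was -0.01 with the slide block and within slide 1, -0.02 with slide as a random block, and -0.10 and -0.04 without tetracycline replicate 3 and control replicate 1. Of 20 genes of catecholamine synthesis and handling, 3 rose and 1 fell (5 and 4 adjusted over the list alone). The vesicular monoamine transporter SLC18A1, the noradrenaline transporter SLC6A2 and DDC rose, with log2 fold changes of 2.45 (SE 0.28), 2.29 (SE 0.28) and 1.22 (SE 0.20). DDC, which makes dopamine from DOPA, was 2.33-fold higher, whereas the secretory granule protein SCG2 was 3.11-fold lower. The list had a median of 0.03 (camera adjusted p = 0.495). Of 24 adrenergic neuroblastoma transcription factors, 1 rose and 3 fell (2 and 4 adjusted over the list alone). MYCN, which is often amplified in neuroblastoma, had a log2 fold change of 2.41 (SE 0.35, adjusted p = 0.0355), and its other probe gave 0.88 and did not pass (adjusted p = 0.0582). ZNF536, DACH1 and SATB1 were 4.35-fold, 2.79-fold and 2.16-fold lower. This list had a median of -0.20 and a camera adjusted p of 0.104 without pairing, 0.0392 after median scaling and 0.0294 with the replicate block, and adjusted p = 0.798 with the block and an estimated correlation. Of 37 genes of the neuronal cytoskeleton and synapse, 2 rose and none fell, adjusted over the list alone likewise: the intermediate filament gene PRPH 2.22-fold and the RNA-binding protein gene ELAVL4 2.04-fold. The median of that list was 0.11, its mean -0.03 and its camera adjusted p 0.771 (0.0432 with array weights).

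Tests on whole lists gave smaller shifts. Without pairing, camera called 6 of 42 lists, 4 higher and 2 lower (13 at an unadjusted p under 0.05), and with the replicate block 9, 6 higher and 3 lower. The block added the adrenergic transcription factors, the endoplasmic reticulum unfolded protein response (27 genes, median 0.21, adjusted p = 0.0148) and histone genes (30 genes, median 0.17, adjusted p = 0.0148). With an estimated correlation camera called 0 lists in either fit (1 and 0 at an unadjusted p under 0.05 without and with the block), the smallest adjusted p being 0.712 and 0.763. The directional set test fry called 0 as well (1 and 11 at an unadjusted p under 0.05). Its test for changes in either direction called 0 lists without pairing and 20 with the block (2 and 28 at an unadjusted p under 0.05). Without tetracycline replicate 3 camera called 3 lists, and without control replicate 2 or 3 it called 10.

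The lists of neurotransmitter receptors, striated muscle genes, endothelial and vascular genes, and blood and immune cell markers were higher (adjusted p = 0.0247 for each), with medians of 0.15, 0.16, 0.24 and 0.42. They had adjusted p = 0.712, 0.712, 0.822 and 0.712 with an estimated correlation. Without the filter on dim probes the medians of the striated muscle and endothelial lists were -0.234 and -0.0820. The striated muscle list was not called with normexp (adjusted p = 0.120), without the filter (0.743), with the filter on all 6 arrays (0.194) or with scan period as a block (0.0692). It was not called with slide as a fixed or a random block (0.234 and 0.0961) or within slide 1 (0.238) either. The receptors were not called with the mean of a gene's probes (0.0508), scan period as a block (0.0692), slide as a fixed or a random block (0.248 and 0.188) or within slide 1 (0.245). The endothelial list was not called after median scaling (0.0513) or without the filter (0.176), nor the immune markers with slide as a random block (0.0861). The receptor call was lost without tetracycline replicate 2 or 3 or control replicate 1 (adjusted p = 0.144, 0.0908 and 0.265), and the immune call without tetracycline replicate 2 or control replicate 1 or 3 (0.144, 0.0668 and 0.0787). The muscle call was lost without tetracycline replicate 3 or control replicate 1 or 2 (0.205, 0.205 and 0.0767), and the endothelial call without the same arrays (0.405, 0.192 and 0.151).

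Of 33 neurotransmitter receptors, 3 rose and 1 fell (7 and 2 adjusted over the list alone). Besides HTR3A, the dopamine receptor DRD2 rose 4.79-fold and the nicotinic receptor subunit CHRNA3 2.02-fold, while the opioid receptor OPRM1 was 2.01-fold lower. Of 22 striated muscle genes, 1 rose, the troponin gene TNNC1, by 5.78-fold (6 rose and 1 fell adjusted over the list alone). TNNC1 was well above background on 1 of 3 control arrays. The muscle genes ACTC1 and TNNT1, brightest among those that did not pass, had log2 fold changes of 0.07 and 0.65. None of 19 endothelial and vascular genes passed (3 rose adjusted over the list alone), and RHOA and VEGFB had values of 0.05 and 0.17. Of 10 blood and immune cell markers, 1 rose, the actin-bundling protein gene LCP1, by 7.14-fold (4 rose adjusted over the list alone), whereas CORO1A and CD4 had log2 fold changes of 1.10 and 0.19 and did not pass.

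MYC and MYCN targets and ribosomal proteins were lower, with medians of -0.22 and -0.16 (adjusted p = 0.0011 and 0.0075, both adjusted p = 0.822 with an estimated correlation). Of 52 MYC and MYCN targets, 36 were lower in all 3 experiments and 1 higher. The only member called was MYCN itself, which rose (1 rose and 1 fell adjusted over the list alone). NME2 and EIF4A1 had log2 fold changes of -0.08 and -0.18 and did not pass. The list's call was lost without tetracycline replicate 2 (adjusted p = 0.144) or control replicate 3 (0.244) and without the filter on dim probes (0.444, at an unchanged median of -0.22), and within slide 1 its median was -0.04 (0.576). With slide as a fixed or a random block the adjusted p was 0.579 or 0.441. Within scan period 1 its median was -0.16 (0.0029). The ribosomal list had medians of 0.07, -0.19 and -0.36 in pairs 1, 2 and 3, and 9 of its members were lower in all 3. Random lists matched on mean expression had medians centred on -0.10 (middle 95% from -0.14 to -0.07), so much of its shift was shared by bright genes. Whether the rest is particular to the list is open, as the random lists leave out members that vary together. None of 49 ribosomal protein genes passed, adjusted over the list alone likewise, and RPS2 and RPLP2 had values of 0.16 and -0.27. The RPS2 value lacks tetracycline replicate 3, and pairs 1 and 2 gave 0.05 and -0.09. Other probes of RPS2 gave -0.24 to -0.58. The ribosomal call was lost after quantile normalization (median -0.01, adjusted p = 0.634), with array weights (median 0.01), with the mean of a gene's probes (median -0.12, adjusted p = 0.152), without the filter on dim probes (adjusted p = 0.743, at an unchanged median of -0.16), within scan period 1 (median -0.07, adjusted p = 0.223), and without tetracycline replicate 3 (adjusted p = 0.979) or control replicate 2 (0.171).

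The lists of G1/S, G2/M and integrated stress response genes were not called without pairing or with the replicate block. Of 53 G1/S and DNA replication genes and 59 G2/M and mitosis genes, none passed, adjusted over each list alone likewise. Their medians were -0.10 and -0.05 (camera adjusted p = 0.199 and 0.946), against 0.02 and 0.08 after median scaling, which raised the median of all genes by 0.12. Both were called higher within slide 1 (medians of 0.23 and 0.18, adjusted p = 0.0014 for each), which rests on a single control array with 1 residual degree of freedom. With slide as a random block they were called higher as well (medians of 0.18 and 0.14, adjusted p = 0.0256 for each). Only slide 1 held more than 1 array, so that fit leans on the same arrays and is not separate support. Both lists were called lower without control replicate 2 (-0.32 and -0.20, adjusted p = 0.0014 and 0.0425). The G2/M list was called higher without control replicate 3 (0.19, adjusted p = 0.0055). MCM7, TYMS, CKS1B and UBE2C had log2 fold changes of -0.39, -0.13, -0.09 and -0.03. The direction of both lists differed between experiments, with medians of -0.15, 0.32 and -0.58 for G1/S and 0.05, 0.13 and -0.26 for G2/M in pairs 1, 2 and 3.

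Of 40 integrated stress response genes, 1 rose and 1 fell, adjusted over the list alone likewise: ATF3 2.77-fold higher and VLDLR 2.43-fold lower. The list had a median of 0.03 (adjusted p = 0.361). It was called higher without control replicate 3 (median 0.12, adjusted p = 0.0213), and its median ran from -0.10 to 0.18 when single arrays were left out. Of 30 genes of cadherins and junctions, 3 rose and 2 fell (7 and 3 adjusted over the list alone), among them the claudin CLDN4, 7.07-fold higher, CDH11, 2.88-fold higher, PKP2, 1.97-fold lower, and GJA1. None of 18 inflammatory and NF-kB genes passed (1 fell adjusted over the list alone), with NFKBIA at -0.33 and NFKBIE at -0.42. The camera adjusted p of these lists was 0.104 and 0.0888, with medians of 0.22 and -0.12, and the cadherin list was called higher without control replicate 2 (adjusted p = 0.0425). The inflammatory list was called lower relative to the other genes after median scaling (adjusted p = 0.0392), where its own median was 0.01. It was called lower as well with every probe on its own (0.0480) and without control replicate 1 or 2 (0.0142 and 0.0178).

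**Figure D2:**
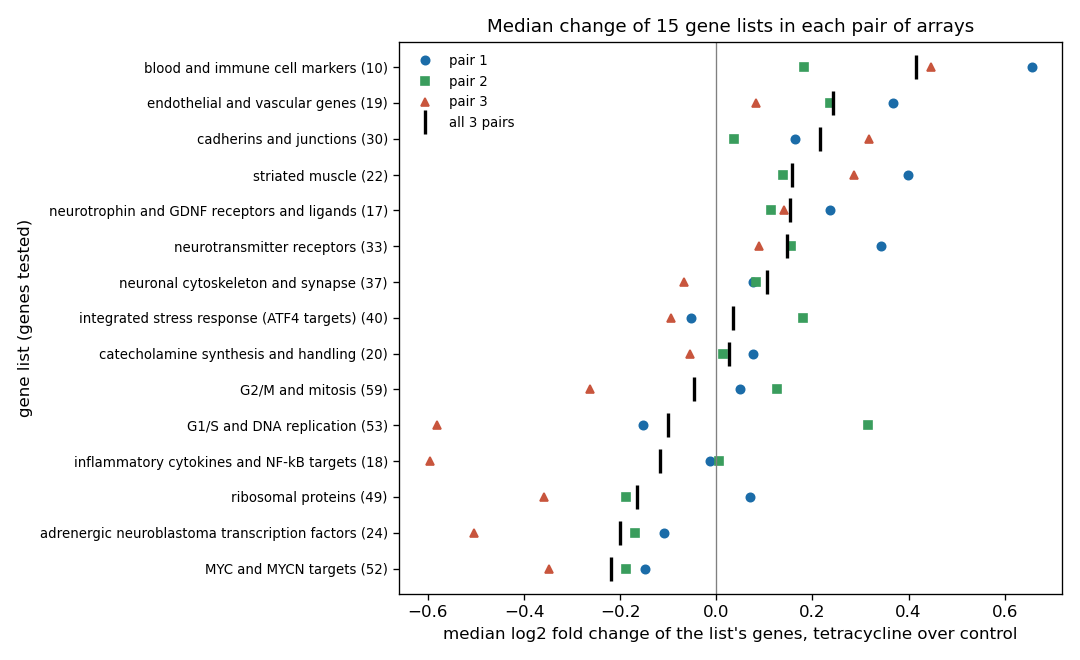
Median log2 fold change, tetracycline over control (x axis), of the genes of 15 lists (y axis, with the number tested); coloured points give each same-numbered pair of arrays and black bars the median of the mean change. MYC and MYCN targets lay below 0 in each pair and blood and immune cell markers above it.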

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

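Scan period block and subsets, slide 1 alone, slide as a random block, the trend with the random block, and all alternatives for the paired test except the fixed block and no block were chosen after the data were seen, as was the way array weights were estimated. Without pairing, the count of genes was 0 under every scaling, filter and probe rule, with the fixed replicate block and the slide block, and leaving out any array. It was 333 with the random replicate block (348 with a trend and robust prior), 487 with array weights, 14 with scan period as a block and 105 with slide as a random block. The counts changed at least 2-fold were 267, 275, 305, 14 and 105. In pairs, 333 genes became 202 (quantile normalization), 184 (median scaling), 1 (no filter) and 3559 (array weights). They became 0 (fixed replicate block), 0 (no replicate block) and 0 to 181 leaving out an array. Without the filter more genes were tested, but the consensus correlation was also lower, 0.656 against 0.887. The genes at an unadjusted p under 0.05 in the paired test went from 2977 to 2341. The paired 2-fold count of 267 became 1 (no filter), 602 (array weights), 0 (fixed replicate block), 0 (no replicate block) and 0 to 181 leaving out an array. Median scaling shifted the median of all genes by 0.12. The share of higher calls, 61.6% of 333, was 59.4% (quantile normalization), 59.2% (median scaling), 52.2% (normexp), 51.3% (filter on all 6 arrays), 50% (array weights) and 47.4% to 81.8% leaving out an array.

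CASZ1 kept its direction under all alternatives, and its log2 fold change without each array was 2.02 to 4.14. It passed at 3.24 with the random replicate block (also with a trend) and at 2.95 with array weights. The number of lists called went from 6 to 12 with every probe on its own, 10 with the slide block, 10 on slide 1 alone, 0 with an estimated correlation and 0 with directional fry, both also 0 with the replicate block, and 3 to 10 leaving out an array: 3 without tetracycline replicate 3, and 10 without control replicate 2 or 3. Median changes turned sign, with the main or the other value called, for striated muscle (-0.234) and endothelial genes (-0.0820) without the filter, ribosomal proteins with array weights (0.0104), inflammatory genes with median scaling (0.00516), and G1/S and G2/M genes: 0.23 and 0.18 with the slide block and on slide 1 alone, 0.18 and 0.14 with slide as a random block, and for G2/M -0.204 to 0.187 leaving out an array (0.187 without control replicate 3). The causes were not tested. Of the 52 genes that the naming rule takes and that passed in pairs, none turned sign under the alternatives for the paired test, of which the filter on all 6 arrays left 31 to test. The number still called was 39 after quantile normalization, 43 after median scaling, 46 with normexp and 1 without the filter. It was 33, 14 and 0 without tetracycline replicates 1, 2 and 3, and 31, 15 and 0 without control replicates 1, 2 and 3. The fixed replicate block added the calls of 3 lists, and the random block those of genes, of CASZ1 and of the adrenergic list; neither changed another call. The slide block and slide 1 alone rest on a single control array and leave 1 residual degree of freedom. Slide as a random block draws its correlation from slide 1, the only slide with more than 1 array. The paired test on scan period 1 alone was not run, as its correlation could not be estimated. Where an array left out leaves a lone member of a pair, that array is taken to vary like the rest. Signal over background limits the folds of genes seen in only 1 group to bounds.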

Other observations

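Several tests in this part were chosen after the results were seen: all splits except those for the unpaired gene count, the sizes of the changes after quantile normalization, the matched random lists, the tests on scan period 1, on slide 1 and with slide as a random block, the estimated correlation as a test of the MYC list, and the comparisons between pairs. Among lists not described above, Wnt pathway genes moved both ways in the paired test: of 26 tested, DKK2, LGR5 and the Frizzled receptor gene FZD4 (log2 fold change -1.52, SE 0.21) fell and DKK3 (1.20, SE 0.16) rose (6 fell and 4 rose adjusted over the list alone). The list had a median of -0.14 (camera adjusted p = 0.104) and was called lower after median scaling (median -0.02, adjusted p = 0.0483). Of 15 smooth muscle and actin contractile genes, CNN1 (2.07, SE 0.24), TPM1 (1.37, SE 0.16) and ACTN1 (1.34, SE 0.20) rose and none fell (4 rose and 2 fell adjusted over the list alone), with a median of -0.04 and a mean of 0.28 over the list. Of 49 genes of the extracellular matrix and integrins, COL3A1 (-2.21, SE 0.30), COL4A2 (-1.45, SE 0.15) and FN1 (-1.22, SE 0.19) fell and none rose (10 fell and 3 rose adjusted over the list alone). These members were named after their values were seen. MYC, a member of the MYC and MYCN target list and outside the rule too, had a log2 fold change of -2.07 and did not pass (adjusted p = 0.0561), with pair values of -0.98, -2.33 and -2.90.

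The first pattern is the set of 333 genes called in pairs. Splits of the 6 arrays are too few for a share under 0.05. Without pairing, the real split gave 0 genes and the highest of the other splits 0, so 10 of 10 splits gave as many, and the same holds for changes of at least 2-fold (10 of 10). Among the 4 splits that part all pairs, the real one gave 333 genes (267 changed at least 2-fold) and the highest other 0, so 1 split of 4 gave as many in each case. Of the splits that part 1 pair, the 2 that part pair 3 gave 826 and 815 genes with the same fit, and the others gave 0. These 2 set replicate 1 against replicate 2 and, within pair 3, tetracycline against control. They carry the tetracycline difference of pair 3, so they do not measure chance. Which of the differences these calls follow was not tested.

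A difference in overall signal between the groups' arrays was weighed against these calls. After quantile normalization 202 genes were called, of which 194 were among the 333, and the 75th percentiles of the unscaled signal overlapped between the groups. Over all 333 genes the median size of the log2 fold change was 1.51 before and 1.52 after. The values before were already scaled to each array's 75th percentile. Quantile normalization moved the median of all genes by only 0.0394, so these sizes could hardly have changed and decide nothing. For the 139 genes no longer called the median size was 1.14 before and 1.17 after. Their median paired SE went from 0.168 to 0.217, which ended those calls. The explanation stays open for both the number and the size of the changes. In pairs 1 and 3 the tetracycline and control arrays lay on different slides. With slide as a random block 105 genes were called, of which 72 were among the 333. A difference between slides therefore stays open for these calls too. An effect of tetracycline on mitochondrial translation, rather than of CASZ1b, could raise the integrated stress response list. Its median was 0.0342 (adjusted p = 0.361), inside the bounds of -0.2 to 0.2 set beforehand for no such effect, but its members went both ways, with 8 higher and 7 lower in all pairs, and it was called higher without control replicate 3 (median 0.123, adjusted p = 0.0213), so the median decides nothing. The list of mitochondrial unfolded protein response and mitochondrial translation genes, 61 tested, had a median of -0.10 (camera adjusted p = 0.461). Of these, 11 were higher and 23 lower in all pairs, and no outcome had been set beforehand for this list. With no array of tetracycline-treated cells lacking CASZ1b, an effect of the drug cannot be told apart from one of CASZ1b. An effect of CASZ1b remains an untested hypothesis.

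The second pattern is the lower median of MYC and MYCN targets while MYCN rose. The other MYCN probe had a smaller difference and did not pass, and MYC was lower in every pair but did not pass. Whether the list followed either gene was not tested. Bright genes reading lower on the tetracycline arrays is argued against as the whole of the shift. Random lists matched on mean expression had medians centred on -0.051. The median of -0.219 lay below the middle 95% of 10000 such lists (-0.108 to 0.0184). They were drawn gene by gene, so the band leaves out members that vary together. Several lists that camera did not call, such as TGF-beta and BMP genes, also lay outside theirs. The arrays of replicate 3 alone are argued against as well, since on scan period 1 alone the list had a median of -0.16 and an adjusted p of 0.00288, with medians of -0.15 and -0.19 in pairs 1 and 2. Leaving out control replicate 3 by itself ended the call (adjusted p = 0.244). The period 1 call needed control replicate 1: on slide 1, which lacks it, the median was -0.04 (adjusted p = 0.576). With slide as a fixed or a random block the adjusted p was 0.579 or 0.441, so a difference between slides stays open. Members that vary together between arrays remain a candidate explanation, with an adjusted p of 0.822 once the correlation is estimated. A total of 2 of 10 splits gave the list a camera p as small, 2.6e-05 for the real split and 1.02e-08 for the smallest other, and the splits are too few for a share under 0.05. With the replicate block, among the 4 splits that part all pairs, the real one gave a camera p of 1.14e-07 and the smallest other 0.000976, so 1 gave a p as small. Splits that part 1 pair gave a camera p down to 0.000262 with that block. They compare tetracycline with control in the parted pair alone, so they do not measure chance. A response to CASZ1b stays open and untested.

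For the number of lists called, 7 of 10 splits gave as many as the real 6, the highest other giving 16. With the replicate block, among the 4 splits that part all pairs the real one gave 9 lists and the highest other 4, so 1 gave as many. The splits that part 1 pair gave up to 8 lists with that block, but there the group term is the tetracycline difference of the parted pair alone. Pair 3 differed more between its arrays than the other pairs: the SD over genes of the log2 difference was 1.00, against 0.45 and 0.50 in pairs 1 and 2. Over the 333 called genes the median size of the log2 difference was 1.21, 1.46 and 1.73 in pairs 1, 2 and 3. Of all genes, 61.8% had the same sign in pair 3 as in the mean of pairs 1 and 2. The paired test takes the difference to be shared by all pairs. Whether it differed between scan periods stays open, as period 2 held 1 array per group. Differences in pairs 1 and 2 correlated at r = 0.581 across genes, which are not independent replicates, and those in pair 3 at 0.341 and 0.334 with pairs 1 and 2.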
